A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

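Single-cell RNA was counted in 7 libraries of budding yeast (Saccharomyces cerevisiae). Per the labels, 3 wild-type libraries form a time course (exponentially growing cells at 0 h, and cells aged for 24 h or 48 h in devices the labels call MADs and collected on magnets). The other 4 libraries are the outer 25% tails of 2 fluorescence sorts, each keeping live cells rich in bud scars. One sort separated 48 h cells by the level of a fluorescently tagged Srp40 protein; the genotype names yEmCherry as its tag and the protocol mNeon, so the signal sorted on is not certain. The other separated 24 h cells by what the labels call the MMP ratio, in a strain carrying mNeonGreen behind a COX4 presequence and Tim50 fused to mCherry. Every group holds 1 library. The labels name 2 droplet 3' kits for tagged RNA molecules and do not state which library was made with which.

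The deposited files hold raw counts of unique molecular identifiers (UMIs) per barcode and gene, not normalized. Per the submitters' processing notes, the tools were kallisto 0.48.0 and bustools 0.41.0 and the genome builds sacCer3 and R64; their roles and settings are not stated. The values show that barcodes were not filtered before deposit. Of the features, 5924 matched the reference annotation of assembly R64, from which symbols and coordinates were taken (1-based), and 686 did not, among them spacer and retrotransposon features. How reads shared between near-identical copies (the HXT6 and HXT7 pair, the PAU family, ribosomal protein paralogs, the ribosomal DNA repeats) were assigned is not stated, so values of single copies are uncertain.

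A barcode was called a cell at or above the lowest point of the density of log10 UMI counts between background and cells, searched from 200 to 10000 UMIs. The library of the high MMP tail had no such valley, and the rule fixed for that case was used, 10% of the 99th percentile of its top 3000 barcodes. This put its threshold at 2826 UMIs, close to its background mode of 1622 UMIs, with 40.0% of the file's UMIs in cells. Some of the barcodes called cells in that library may therefore be background. UMIs were summed over the cells of each library and scaled to each library's total (CPM). Comparisons used log2 ratios of CPM with a pseudocount of 1 CPM, over genes with at least 100 UMIs in the pair of libraries and at least 30 CPM in one. With 1 library per group there was no test, and no p-value or standard error is given; no difference has a replicate check. Ratios carry exact 95% intervals (Clopper-Pearson on the share of the pooled UMIs) and single levels exact Poisson intervals; both cover counting error only. Genes were counted as different at 2-fold. The genes to be named were the 8 largest and 8 smallest log2 ratios of each comparison, up to 4 members of each list that stood apart, and SRP40, FIT2, FIT3, CIT2, TIM50, URA3, HO and the mating-type genes.

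For 39 gene lists, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart where its median lies below the 2.5th or above the 97.5th percentile, as a description of these libraries. Members at least 1.5-fold higher or lower were counted. Correlations across genes used genes with at least 100 UMIs in every library concerned. Where a pair of comparisons shares a library, 100 Poisson resamplings of unchanged libraries gave the values expected from counting noise. Across cells, Spearman's rho was computed on cells thinned to 1000 UMIs, beside 1000 pairs of random matched lists. Each time-course library was clustered alone (10000-count log normalization, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). A cluster was named for the class of fixed markers with the highest median log2 ratio, when that median was at least 1 over at least 3 detected markers and at least 2 of them, more than of any other class, were among its top 10 genes. This naming rule was set after the clusters were seen. Scrublet called at most 9 doublets per library, so doublets are not considered removed under any setting.

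The groups, comparisons, gene lists, marker genes and most alternatives were fixed before the data were examined. The fixed alternatives change the cell calling, the scaling (TMM factors from edgeR 4.0.16, median-of-ratios factors from DESeq2 1.42.0), the filter, the pseudocount, the weight of each cell, the background and the clustering resolution. Chosen after seeing the data were the matching of cells on total UMIs (bins of 0.1 log10), the subtraction of each library's own background, a minimum of 3 times the background mode, the removal of ribosomal DNA features from the signatures, a split of cells into 3 equal groups by UMIs, and the correlations across genes under matching, thinning and per-cell means. Tolerances for calling a correlation moved (0.1) or a list median moved (1.5-fold) were set while the computations were written, and counting every change of sign of a list as a reversal was settled after values had been seen. The computations were tested on simulated data drawn from the real means and depths. For the comparisons only Poisson counting noise was simulated, with no variation between libraries or cells. Those runs therefore check the computations and give no rate of false calls for libraries without replicates. In each of the 5 comparisons 100.0% of genes changed 3-fold were called at 2-fold, 0.0% of those changed 1.5-fold, and 0 unchanged genes; these runs covered 3463, 3568 and 3688 genes for the time course (24 h against 0 h, 48 h against 0 h, 48 h against 24 h), 4501 for the Srp40 sort and 4374 for the MMP sort. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.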

Results

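Messenger RNA was counted in single budding yeast cells as they aged, and in aged cells sorted by a nucleolar or a mitochondrial reporter. The series title states the interest: independent processes of ageing that compete over the fate of a cell. The wild-type time course comprised 1 library each at 0 h (2291 cells, 87403348 UMIs in cells), 24 h (1947 cells, 62732367 UMIs) and 48 h (2487 cells, 57120995 UMIs). The Srp40 sort of 48 h cells gave 1594 cells and 35096363 UMIs in the high tail, and 5835 cells and 56376191 UMIs in the low tail. The MMP sort of 24 h cells was shallower, with 1107 cells and 8359838 UMIs in the high tail and 1085 cells and 4994385 UMIs in the low tail. Median UMIs per cell were 35480 at 0 h, 27320 at 24 h and 13370 at 48 h, 18202.5 and 7706 in the high and low Srp40 tails, and 4804 and 3754 in the high and low MMP tails. Free RNA, estimated from empty barcodes, made up 21.4% of the cell UMIs in the high MMP tail and 11.2% in the low MMP tail, and between 0.104% and 2.82% in the other libraries. Each group is 1 library, so every difference below lies between libraries and has no replicate check, and intervals in brackets are 95% and cover counting error only.

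Genes specific to a or alpha cells matched the strains named in the labels. MATALPHA1, from the alpha allele itself, had 0 UMIs in all 7 libraries. The 7 a-specific genes, which include the a-factor precursors, summed to 1914 and 788 CPM in the high and low MMP libraries, whose strain is labelled MATa, and to between 22.4 and 39.9 CPM in the other 5 libraries. The alpha-specific genes summed to 74.3 and 81.5 CPM in the MMP libraries and to between 1558 and 4141 CPM in the others. The libraries of each comparison come from 1 strain, so this check says nothing on age or on the tail of a sort.

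The first question was how 24 h of ageing differed from growing cells. Stress, respiratory and hypoxic genes were higher in the 24 h library, and genes that make ribosomes were lower. DAN1 (YJR150C, chromosome X, 708811 to 709707), a cell wall mannoprotein gene of anaerobic growth, stood at 221 CPM against 0.0572 CPM at 0 h, from 13849 and 5 UMIs. Its ratio without the pseudocount was 3859-fold [1653 to 11890]. HSP26, a small heat shock protein gene, was 144.5-fold higher [137.5 to 152.0], at 2568 against 17.8 CPM. TDH1, an isoform of glyceraldehyde-3-phosphate dehydrogenase, was 122-fold higher [118 to 126], and the high-affinity hexose transporter gene HXT6 286-fold [251 to 328], although HXT6 and HXT7 are near-identical and may share reads. On the other side, the alpha-factor gene MF(ALPHA)2 was 3.92-fold lower [3.85 to 3.99] and ATO3, an ammonium exporter gene, 3.28-fold lower [3.17 to 3.39].

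Of the 24 measured members of the general stress response of Msn2 and Msn4, all 24 were at least 1.5-fold higher at 24 h, with a median log2 ratio of 3.57 (3.45 relative to the median of all genes, and between 2.96 and 4.95 under the alternatives). SIP18 was 34.8-fold higher and the trehalose gene TPS1 2.94-fold. All 11 hypoxic and anaerobic genes were higher (median 3.80, 2.30 with no expression filter and 2.99 with a pseudocount of 10 CPM), DAN1 the most, then TIR4 at 59.3-fold, and AAC3, a mitochondrial ADP/ATP carrier gene, the least at 1.89-fold. Of the nuclear genes of the respiratory chain, 22 of 24 were higher and 0 lower (median 1.24), with the succinate dehydrogenase gene SDH2 at 4.03-fold [3.87 to 4.19]. The TCA cycle list had 9 of 11 members higher (median 1.19, MDH1 at 3.07-fold) and the nuclear ATP synthase genes 11 of 14 (median 0.83). The retrograde list, genes that respond to mitochondrial dysfunction, had 6 of 8 higher and 1 lower (median 1.24), with CIT2, the peroxisomal citrate synthase gene, at 4.96-fold [4.78 to 5.15]. Genes of gluconeogenesis were 5 of 6 higher (median 1.73, between 0.98 and 3.54 under the alternatives, PCK1 at 9.31-fold), the hexose transporters 5 of 7 higher and 1 lower (HXT1, 2.36-fold lower), and the zinc regulon of Zap1 4 of 5 higher (median 1.23, ZRT1 at 28.6-fold). Heat shock chaperones were 11 of 23 higher and 1 lower (median 0.58, 1.18 without cells holding daughter gene UMIs), cell wall integrity genes 6 of 11 higher (median 0.83, 1.78 without these cells), and amino acid biosynthesis genes 12 of 28 higher (median 0.37).

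Ribosome biogenesis and nucleolar genes had 37 of 59 members lower and 0 higher, with a median of -0.65 (-0.77 relative to all genes); NOP15 was 2.65-fold lower [2.53 to 2.77] and SRP40 itself (YKR092C, chromosome XI, 612665 to 613885) 1.72-fold lower [1.68 to 1.75]. The cytosolic ribosomal proteins had 25 of 136 members lower and 0 higher (median -0.40), with RPL39 2.30-fold lower. RNA polymerase I genes (4 of 11 lower, median -0.28), G1/S genes (1 of 14 lower, median -0.23, turning to 0.42 without cells holding 2 or more daughter gene UMIs) and alpha-specific genes (2 of 4 lower, median -0.66) lay on the same side. The iron regulon of Aft1 and Aft2 did not stand apart, with 4 of 16 members higher and 3 lower; FIT3 and FIT2, cell wall mannoproteins that retain iron-bound siderophores, were 5.12-fold and 4.71-fold higher, and the siderophore transporter gene SIT1 2.70-fold lower [2.53 to 2.89].

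Of 3711 genes, 394 were at least 2-fold higher and 27 lower (93.6% of these higher). With thinned cells these were 748 and 149, with every cell weighted alike 794 and 137, without cells holding daughter gene UMIs 827 and 161, and under the filter of 500 UMIs and 100 CPM 203 and 17. The split was 297 to 131 (69.4%) under TMM and 320 to 94 (77.3%) under median-of-ratios scaling, which moved the median of all genes from 0.12 to -0.14 and -0.09, and the small shift of glycolysis genes (3 of 16 higher, median 0.21) turned to -0.05 and -0.002. Growing cells were never in an ageing device or on a magnet, so age and handling cannot be told apart in either comparison with 0 h.

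**Figure D1:**
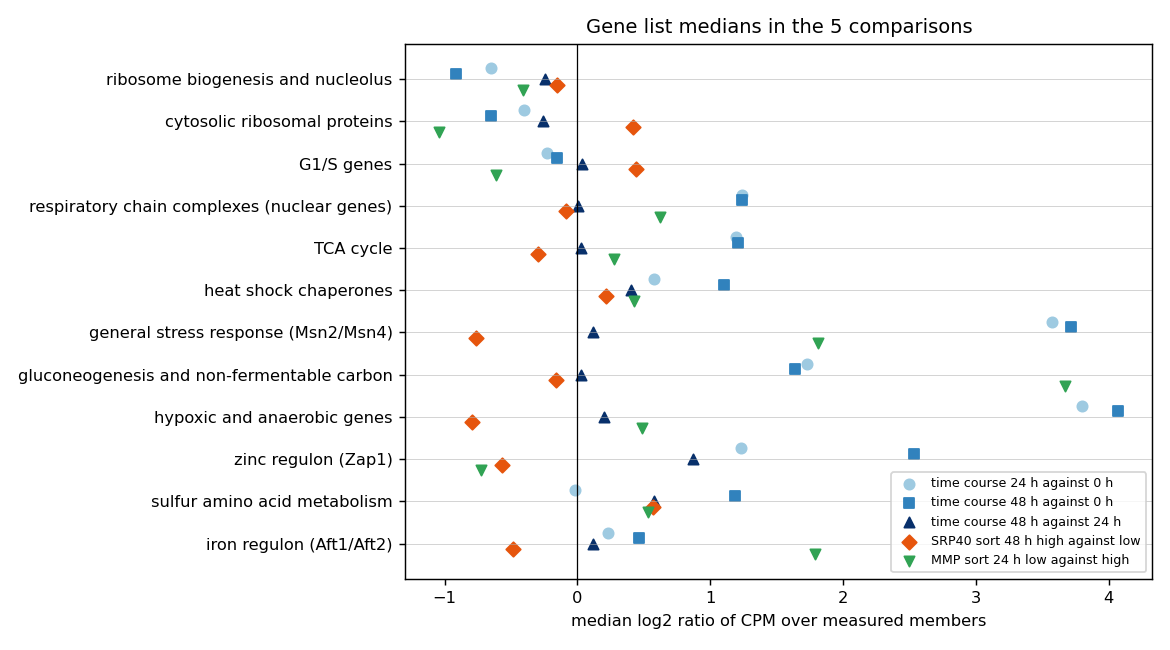
Median log2 ratio (horizontal axis) of 12 gene lists in each of the 5 comparisons, with the list's name on the vertical axis. Stress and hypoxic genes lie far above 0 in the 24 h and 48 h libraries against 0 h, ribosome biogenesis genes and ribosomal proteins lie below, and the MMP-low library has the highest median of the iron regulon, at 1.79.

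The comparison of 48 h with 0 h asked the same at the later age. NTS1-2, an annotated spacer of the ribosomal DNA repeat, entered the leading features, at 10705 CPM against 55.0 at 0 h, 194.5-fold higher [189.0 to 200.1]; it stood at 2767 CPM at 24 h. YLR154W-E, another feature of the repeat, was 276-fold higher [261 to 293]. HSP26 was 250-fold higher [238 to 263], DAN1 5633-fold [2414 to 17350], and HSP12, a membrane-protecting stress protein gene, 31.7-fold [31.2 to 32.3]. The zinc genes ZRT1, which encodes the high-affinity transporter, and ZPS1 were 51.9-fold [49.1 to 55.0] and 41.9-fold [38.9 to 45.1] higher. ATO3 was 4.92-fold lower [4.72 to 5.13], the low-affinity hexose transporter gene HXT1 3.83-fold lower [3.70 to 3.96] and HO, the mating-type endonuclease gene, 3.27-fold lower [3.12 to 3.43].

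All 26 stress response members were higher at 48 h (median 3.71, 3.53 relative to all genes, 2.96 with a pseudocount of 10 CPM), as were all 11 hypoxic genes (median 4.07, 2.45 with no expression filter) and all 6 zinc genes (median 2.53, and 1.75 under TMM scaling, where 7 were measured). Respiratory chain genes were again 22 of 24 higher (median 1.24), TCA cycle genes 9 of 11 (median 1.21) and ATP synthase genes 9 of 14 (median 0.87). Retrograde genes were 6 of 8 higher and 1 lower (median 1.20), with CIT2 at 9.09-fold [8.77 to 9.41]. Heat shock chaperones were 14 of 23 higher and 1 lower (median 1.10), the cell wall integrity list 7 of 11 higher (median 1.07, 2.44 without cells holding daughter gene UMIs, PIR3 at 17.6-fold) and the sulfur amino acid list 7 of 11 higher and 2 lower (median 1.19, MET28 at 4.62-fold). Hexose transporters (4 of 7 higher, 1 lower, median 4.26, and between 2.11 and 2.67 with a pseudocount of 10 CPM, the threshold from the top 3000 barcodes, the stricter filter or matched cells) and amino acid biosynthesis genes (10 of 28 higher, median 0.49) lay above their random lists too. FIT3 was 9.70-fold higher [9.18 to 10.2] and FIT2 4.74-fold, while the iron regulon as a list did not stand apart (8 of 19 higher, 3 lower).

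Ribosome biogenesis genes were 51 of 59 lower and 0 higher at 48 h (median -0.92, -1.10 relative to all genes). NSR1, the yeast nucleolin gene, stood at 274 CPM against 715, 2.61-fold lower [2.57 to 2.66], and SRP40 at 159 against 363 CPM, 2.28-fold lower [2.23 to 2.33]. Ribosomal proteins were 89 of 136 lower and 0 higher (median -0.65), with RPL33B 2.67-fold lower. G1/S genes (2 of 14 lower, median -0.15, turning to 0.57 without cells holding daughter gene UMIs) and genes of daughter cells (1 of 10 lower, median -0.27) also lay below their random lists.

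Of 3871 genes, 586 were at least 2-fold higher and 105 lower (84.8% higher), against 397 to 335 (54.2%) under TMM and 415 to 317 (56.7%) under median-of-ratios scaling, and 293 higher under the filter of 500 UMIs and 100 CPM and 925 with none. The median of all genes moved from 0.18 to -0.15 and -0.13, and the glycolysis list (4 of 16 higher, median 0.15) turned to -0.18 and -0.15. The sulfur list turned to -0.30 under a filter of 500 UMIs and 100 CPM, and HO turned to a log2 ratio of 3.25 without cells holding 2 or more daughter gene UMIs. Across 5481 genes the ratios at 24 h and 48 h correlated at r = 0.959 (rho 0.942). Both share the 0 h library; counting noise alone gave r = 0.408 and a covariance of 0.000801, against an observed covariance of 0.641, and part of the excess may come from the shared library. Of 3691 genes tested in both, 379 were 2-fold higher in both (54.7 for independent lists) and 26 lower in both (0.768). Lists that share the 0 h library are not independent, so these overlaps can also come from that library.

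**Figure D2:**
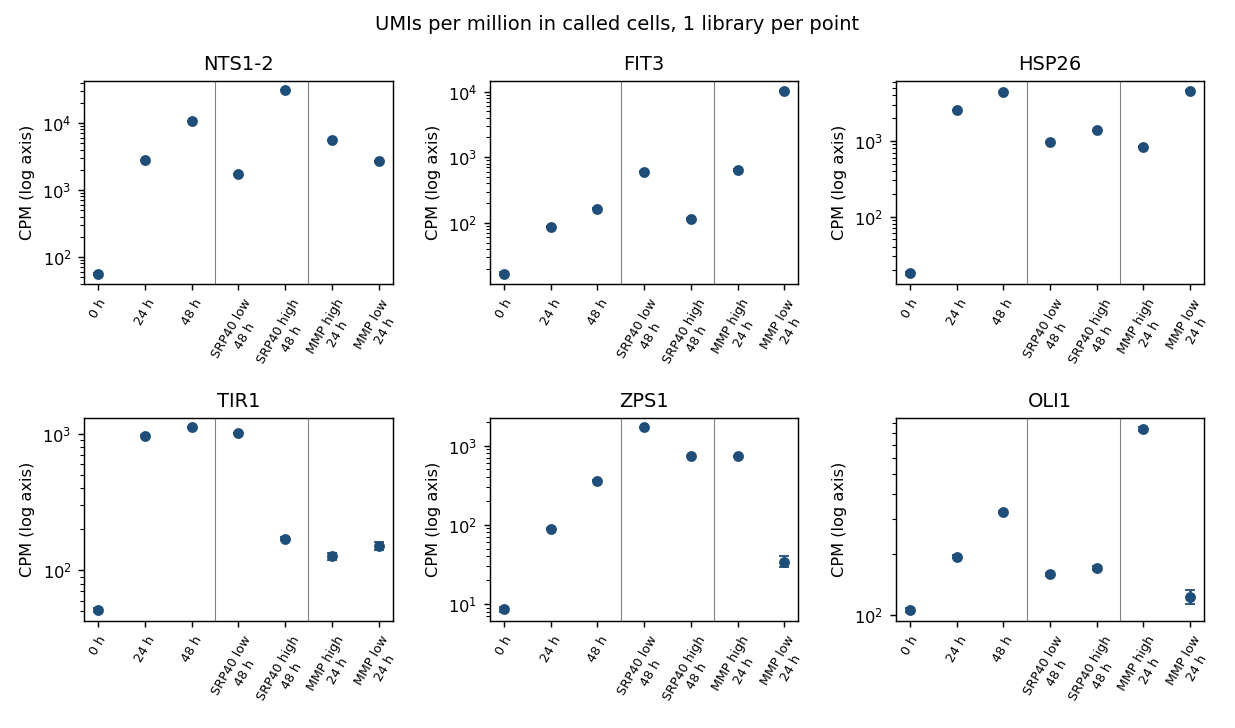
Level of 6 features in CPM on a log axis in each of the 7 libraries, with exact 95% Poisson intervals as bars, mostly smaller than the points. NTS1-2 stood at 55.0, 2767 and 10705 CPM at 0 h, 24 h and 48 h, and FIT3 reached 10402 CPM in the MMP-low library.

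The step from 24 h to 48 h was smaller. YIL082W, a retrotransposon gene, stood at 223 CPM at 48 h against 21.4 at 24 h, 10.4-fold higher [9.85 to 11.0]. Ribosomal DNA features followed, with YLR154W-E 4.53-fold higher [4.48 to 4.57] and NTS1-2 3.87-fold [3.85 to 3.89]. ZPS1 was 4.09-fold higher [3.97 to 4.21], at 360 against 88.1 CPM, and the zinc-regulated alcohol dehydrogenase gene ADH4 3.44-fold [3.37 to 3.52]. The seripauperin genes PAU2 and PAU5 were 6.55-fold [5.96 to 7.22] and 4.42-fold lower [4.17 to 4.68], PCK1, the gluconeogenic carboxykinase gene, 3.02-fold lower [2.85 to 3.20] and the thiamine gene THI4 2.91-fold lower [2.70 to 3.14].

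Zinc genes were 4 of 6 at least 1.5-fold higher at 48 h (median 0.87), heat shock chaperones 7 of 23 (median 0.40, BTN2 at 2.40-fold) and cell wall integrity genes 4 of 11 (median 0.45). The sulfur list was 5 of 11 higher and 1 lower (median 0.58), turning to -0.14 under the stricter filter. Ribosome biogenesis genes and ribosomal proteins had medians of -0.25 and -0.26 with none of 58 and 136 members beyond 1.5-fold, and the ribosomal proteins turned to 0.12 without cells holding daughter gene UMIs. The stress list (1 of 26 higher, median 0.12) and the hypoxic list (1 of 11 higher, median 0.20) lay above their random lists, but turned to -0.41 and -0.16 when each cell was thinned to 1000 UMIs. Of 3789 genes, 25 were at least 2-fold higher and 5 lower; among cells matched on total UMIs these were 13 and 8, and with thinned cells 26 and 41.

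The ribosomal DNA signal was unevenly spread over cells. Among cells thinned to 1000 UMIs, the median cell held 0 NTS1-2 UMIs at 0 h, 1 at 24 h and 5 at 48 h, and the 95th percentile was 1, 17 and 55. The 10% of cells with the most NTS1-2 held 73.1% of its UMIs at 24 h and 56.2% at 48 h. All 11 ribosomal DNA features together made up 0.0716% of the cell UMIs at 0 h, 0.717% at 24 h and 2.03% at 48 h. Of these features, the spacers NTS2-1 and NTS2-2 had 0 UMIs in all 7 libraries, so the spacer signal is that of NTS1-2 alone. The rRNA genes are not among the features summed, and no UMIs were counted on them. TAR1, a gene antisense to the 25S rRNA, lies inside RDN25-1 (chromosome XII, 454696 to 455070 within 451786 to 455181); NTS1-2 and YLR154W-E have no coordinates in the reference used.

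**Figure D3:**
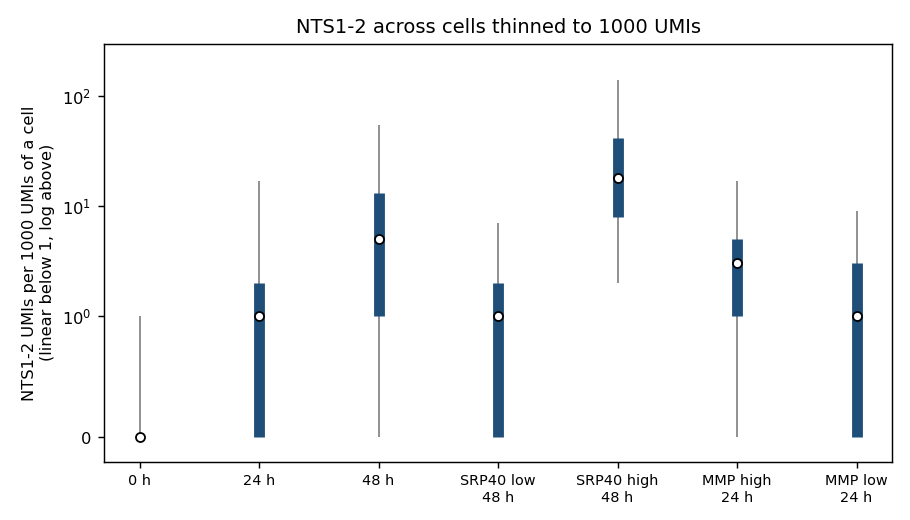
NTS1-2 UMIs per 1000 UMIs of a cell in the 7 libraries; dots are medians, thick bars run from the 25th to the 75th percentile and thin lines from the 5th to the 95th. The median is 18 in the high Srp40 tail and 1 in the low tail.

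Each time-course library was split into clusters of cells, described by their leading genes. At 0 h, 7 clusters formed, of which the daughter-like (21.6% [19.9 to 23.3], exact binomial), S-phase-like (20.1%), G1/S-like (8.77%) and 2 G2/M-like clusters (16.8% and 10.1%) carried their class's markers. The daughter-like name follows the rule alone. That cluster was led by HO, a gene transcribed in mother cells, and its G1/S markers had a median of 1.76 against 1.90 for the daughter markers. An unnamed 0 h cluster of 13.1% was led by AGA1 and SAG1, agglutinin genes of mating, with FUS1 and KAR4 among its top genes. At 24 h, 7 clusters formed, with the same S-phase-like, G2/M-like and daughter-like classes. HO was again among the top genes of the daughter-like cluster, at 127 CPM against 18.8 in the other cells. Its G1/S markers had a median of 1.38 against 2.27 for the daughter markers. An unnamed 24 h cluster (21.0% [19.2 to 22.8]) was led by the stationary-phase genes SPG1 and SPG4, with a median of 5163 UMIs per cell. Another unnamed 24 h cluster, of 9.86% [8.57 to 11.3], was led by PAU5, PAU2 and DAN1. At 48 h, 9 clusters formed, among them unnamed clusters led by SPG1 (17.9%), by DAN1 and TIR4 (13.2% [11.9 to 14.6]) and by NTS1-2 (5.51%). The clusters were found in each library alone, with genes and depths that differ, so their sizes are not compared between ages. Among clusters that did not meet the naming rule, the class with the highest marker median was pheromone (13.1%) and daughter (9.47%) at 0 h, stress (21.0% and 13.7%) at 24 h, and stress (17.9%), iron regulon (324 cells) and G1/S (5.51%) at 48 h. The other unnamed clusters had no class with a median above 0.644. The cluster highest in hypoxic genes (9.86% at 24 h and 13.2% at 48 h) held, at resolutions of 0.3 and 1.0, 17.3% and 5.14% of the 24 h cells, and 18.7% and 5.91% of the 48 h cells.

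The Srp40 sort asked what distinguished 48 h cells with much of this nucleolar protein from those with little. The largest ratios in the high tail were of features in or near the ribosomal DNA, but these features were not all raised alike. Those other than NTS1-2 summed to 20962 CPM in the high and 13169 CPM in the low tail. YLR154W-E, at 7246 and 359 CPM, and TAR1, at 2163 and 615 CPM, together differed by more than these sums did. The other features in the sums were therefore lower in the high tail on balance. NTS1-2 reached 30670 CPM against 1729, 17.7-fold higher [17.6 to 17.9]; YLR154W-E was 20.2-fold higher [19.9 to 20.5], TAR1 3.51-fold [3.47 to 3.56] and YLR162W (chromosome XII, 489573 to 489929) 46.9-fold [40.3 to 54.8]. Lowest in the high tail was SNZ1, a vitamin B6 synthesis gene, at 38.3 against 350 CPM, 9.13-fold lower [8.64 to 9.65], followed by the anaerobic mannoprotein genes TIR4 and TIR1 at 6.40-fold [6.03 to 6.80] and 5.93-fold lower [5.77 to 6.09]. FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) was 5.25-fold lower [5.08 to 5.43]. The SRP40 mRNA was close to equal, at 77.3 CPM in the high and 79.4 in the low tail (ratio of low to high 1.03 [0.979 to 1.08]), and its sign turned under TMM scaling (0.13). The labels describe a sort on Srp40 protein, with the tag named differently in genotype and protocol, and the mRNA does not check it.

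Ribosomal proteins were 30 of 136 higher and 0 lower in the high tail (median 0.42, 0.62 relative to all genes), sulfur amino acid genes 6 of 13 higher (median 0.57, MET17 at 2.40-fold) and G1/S genes 3 of 12 higher (median 0.44, with PCL1 2.59-fold higher and the DNA polymerase gene POL1 2.20-fold). Histones (2 of 10 higher, median 0.33), heat shock chaperones (2 of 23, median 0.21), amino acid biosynthesis genes (4 of 28 higher, 2 lower, median 0.17) and RNA polymerase I genes (1 of 14, median 0.04) also lay above their random lists. Amino acid biosynthesis genes turned to -0.052 in thinned cells. RNA polymerase I genes turned to -0.11 in cells matched on total UMIs, and changed sign under further settings listed with the processing. The stress response was 16 of 27 lower and 0 higher (median -0.76, -0.56 relative to all genes), hypoxic genes 7 of 10 lower (median -0.80, -1.41 without cells holding daughter gene UMIs and -1.48 under the stricter filter), and alpha-specific genes 3 of 4 lower (median -1.38, the a-factor receptor gene STE3 2.72-fold lower). Drug efflux genes were 6 of 11 lower (median -0.64), zinc genes 3 of 7 lower (median -0.57, ADH4 3.17-fold lower) and the iron regulon 9 of 24 lower and 1 higher (median -0.48). Ribosome biogenesis genes had 0 of 59 members beyond 1.5-fold (median -0.16, turning to 0.02 under TMM scaling).

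Of 4613 genes, 28 were at least 2-fold higher and 89 lower (23.9% higher), against 49 to 45 (52.1%) under TMM and 58 to 40 (59.2%) under median-of-ratios scaling; the median of all genes moved from -0.20 to -0.02 and 0.01. Among 1263 cells per library matched on total UMIs the split was 63 to 31 and the shifts of ribosomal proteins (median -0.07), stress genes (-0.21), the iron regulon (-0.05), FIT3 (log2 ratio -2.38 to -0.90) and SNZ1 (to -1.97, no longer the lowest) turned or shrank. NTS1-2 was 23.4-fold higher and the medians of the hypoxic (-1.04), alpha-specific (-1.51) and sulfur (0.70) lists held.

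The MMP sort asked what distinguished 24 h cells of low ratio from those of high ratio. The low library held far more RNA of iron-uptake, gluconeogenesis and stress genes, and less of mitochondrially encoded, zinc and ribosomal protein genes. FIT3 stood at 10402 CPM in the low library against 637 in the high one, 16.3-fold higher [15.9 to 16.8], and FIT2 at 3382 against 528, 6.41-fold [6.20 to 6.63]. LSO1, an iron-responsive gene, was 151-fold higher [76.0 to 350.3] from 720 and 8 UMIs, the acetate transporter gene ADY2 40.6-fold [36.1 to 45.9] and CIT2 5.64-fold [5.38 to 5.92]. ZPS1 was 21.1-fold lower [18.1 to 24.7], ZRT1 8.45-fold lower [7.62 to 9.38], and of the mitochondrial genome OLI1 (chromosome MT, 46723 to 46953), an ATP synthase subunit gene, was 6.85-fold lower [6.31 to 7.45] and COX1, a cytochrome oxidase gene, 5.03-fold lower [4.45 to 5.69]. All features of that genome took 0.134% of cell UMIs in the high and 0.0224% in the low library. How well the 3' kits capture this RNA was not tested.

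The iron regulon had 25 of 28 members at least 1.5-fold higher in the low library and 0 lower, with a median log2 ratio of 1.79 (1.41 relative to all genes). Gluconeogenesis genes were higher in all 15 members (median 3.67, 3.30 relative), the stress response in 24 of 25 (median 1.81, GRE1 at 27.7-fold) and the hexose transporters in 4 of 7 (median 1.51, HXT5 at 52.5-fold). Heat shock chaperones were 10 of 23 higher and 2 lower, with a median of 0.42 that turned to -0.02 under median-of-ratios scaling. Ribosomal proteins were 124 of 136 lower and 0 higher (median -1.04, -1.41 relative to all genes), ribosome biogenesis genes 14 of 58 lower and 1 higher (median -0.41), the 3 measured mitochondrially encoded genes all lower (median -2.76, -1.74 with no expression filter and -2.0 with barcodes of at least 1000 UMIs), and the zinc list 4 of 7 lower (median -0.72, but between -1.96 and -3.06 under both scalings, thinning, ambient subtraction and the stricter filter). Of the cell cycle lists, histones did not stand apart (0 of 10 beyond 1.5-fold, median -0.09). Lower were G1/S genes in 7 of 12 (median -0.62), G2/M genes in 3 of 12 with 1 higher (median -0.49), M/G1 genes in 4 of 9 with 1 higher (median -0.37) and daughter cell genes in 7 of 10 (median -0.77, DSE2 2.25-fold lower). The a-specific genes were 5 of 6 lower (median -1.27, BAR1, the alpha-factor protease gene, 3.36-fold lower), ergosterol genes 6 of 23 lower and 1 higher (median -0.12) and the proteasome had 0 of 30 beyond 1.5-fold (median -0.09). TIM50, the tagged import gene, was 1.21-fold higher [1.12 to 1.32], a sign that turned under TMM scaling (-0.11).

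Of 4596 genes, 1051 were at least 2-fold higher and 152 lower (87.4% higher), against 589 to 412 (58.8%) under TMM and 561 to 462 (54.8%) under median-of-ratios scaling, and 61 lower with all barcodes pooled and 606 higher under the stricter filter. The median of all genes moved from 0.37 to -0.05 and -0.10. Background was estimated at 21.4% of the cell UMIs in the high and 11.2% in the low library, and the M/G1 list turned to 0.15 with all barcodes pooled. It also turned to 0.041 with thinned cells, 0.039 without cells holding daughter gene UMIs and 0.042 with barcodes of at least 1000 UMIs.

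The 2 sorts were set side by side to see whether they separated cells along common genes. Across 4794 genes their log2 ratios, high over low Srp40 and low over high MMP, correlated at r = -0.412 (rho -0.481), with genes not independent replicates. Of 4381 genes tested in both, 58 were 2-fold lower in the Srp40-high library and 2-fold higher in the MMP-low library, against 17.6 for independent lists, among them FIT1, SIT1, POT1 and SNZ1. The opposite pairing, higher in Srp40-high and lower in MMP-low, held 3 genes (0.678). A further 6 were higher in both (4.95) and 5 lower in both (2.40). These overlaps were counted under the main setting only. Genes 2-fold lower in the Srp40-high library numbered 89 there, 45 under TMM, 40 under median-of-ratios scaling and 31 among matched cells. An overlap of 58 could therefore not be reached under these alternatives. On the MMP side the iron regulon was 1.79 and on the Srp40 side -0.48, ribosomal proteins were -1.04 and 0.42, and stress genes 1.81 and -0.76. Among cells matched on total UMIs in both sorts r was 0.161, and with every cell thinned to 1000 UMIs -0.284. The ratios of 24 h and 48 h to 0 h correlated with the MMP ratios at r = 0.555 and 0.585, and with the Srp40 ratios at -0.239 and -0.192, the last pair turning to 0.143 and 0.215 among matched cells. The ratios of 48 h to 24 h correlated with the MMP ratios at 0.383, turning to -0.214 with thinned cells and -0.258 with every cell weighted alike, and with the Srp40 ratios at 0.061, with 0.255 in matched cells, 0.280 in thinned cells, 0.351 with every cell weighted alike and a rho of -0.056. In all 10 such pairs were computed.

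**Figure D4:**
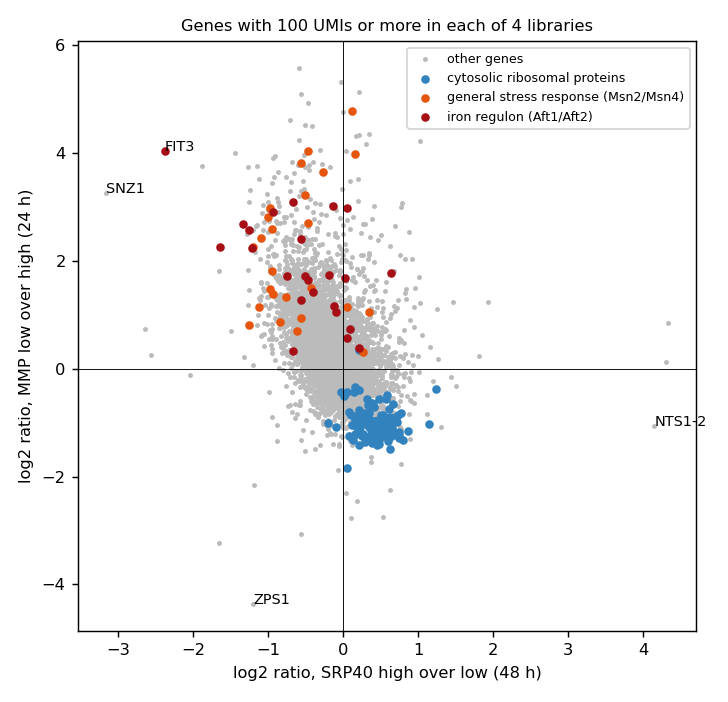
Log2 ratio of high to low Srp40 against log2 ratio of low to high MMP for 4794 genes with at least 100 UMIs in each of the 4 libraries, with ribosomal protein, stress and iron genes in colour. Ribosomal proteins lie on the side of high Srp40 and high MMP, and r over all genes is -0.412.

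Within the unsorted libraries, the question was whether genes of the 2 sorts opposed each other from cell to cell. The values depended on the lists and on the cells taken, and the list pairs were not tested against each other. Signatures of 49 genes each, from the Srp40-high and the MMP-low tails, correlated across cells at rho = -0.035 at 0 h, 0.139 at 24 h and 0.145 at 48 h, inside the range of random matched pairs (-0.051 to 0.034, -0.438 to 0.491 and -0.293 to 0.295). With 100 genes per signature rho was -0.544 at 24 h and -0.097 at 48 h. At 24 h it was 0.251 with 25 genes, -0.033 without ribosomal DNA features, -0.030 without cells holding daughter gene UMIs and -0.064 among the cells with the fewest UMIs. The fixed ribosome biogenesis and iron regulon lists gave -0.163 at 24 h and -0.087 at 48 h, below their random ranges (-0.045 to 0.209 and -0.0007 to 0.153), and 0.029 at 0 h, inside it (-0.052 to 0.047). When the 24 h cells were split into 3 equal groups by total UMIs the value was -0.004, 0.042 and 0.035, from the fewest to the most UMIs. The negative value over all 24 h cells was thus not seen within groups of similar total. At 48 h the values within such groups stayed within 0.1 of -0.087. That tolerance is wider than the value itself, so it does not show that the negative sign held there.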

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

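Chosen only after the results were seen were the tests on background RNA and on shared ribosomal DNA reads for NTS1-2, the tests on background RNA and TMM scaling for the iron regulon, the test without ribosomal and histone genes for the 2 sorts, and the use of matched cells as a setting, although the bounds for matched cells were set before their values were seen.

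A signal lay in barcodes below the cell threshold, which enter the comparisons only in the alternatives that change the cell calling. In the 48 h library 1514 barcodes held at least 500 UMIs but fewer than the 2951 needed to be called a cell, and they carried 3.17% of the UMIs of the file. The same range below the cell threshold held 370 barcodes at 0 h (0.372% of UMIs) and 52 at 24 h (0.0529%), with thresholds of 4677 and 977 UMIs that make the ranges unequal. The 48 h barcodes carried 20101 CPM of NTS1-2, against 10705 CPM in the called cells, and 28158 CPM of the stress list, against 17886. At 24 h the same features stood at 12779 against 2767 CPM and at 25531 against 15246 CPM, and at 0 h at 531 against 55.0 CPM and at 3025 against 2631 CPM. The stationary-phase gene SPG1 stood at 424 CPM in the uncalled 48 h barcodes and 218 in the cells. Whether these barcodes are small, dying or broken cells was not tested.

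NTS1-2 was higher at 24 h and 48 h than at 0 h, and in the high tail of the Srp40 sort. A difference in total UMIs per cell is argued against as the whole cause, since the 48 h to 0 h ratio was 183.1 among cells matched on total UMIs and the ratio in the Srp40 sort 23.4. Free RNA at 48 h was estimated at 0.1045% of the cell UMIs, and NTS1-2 took 1.07%. This argues against free RNA as the whole cause, as far as the barcodes taken as empty were empty. The ratio of 201.1 after the background was subtracted follows from these shares and is not separate evidence. NTS1-2 alone at 48 h, at 10705 CPM, exceeded the 715 CPM of all 11 ribosomal DNA features at 0 h. This argues against reads moving between these features, and the ratio of 28.31 for their sum follows from it. No UMIs were counted on rRNA genes, so reads shared with those were not tested. In the Srp40 sort the log2 ratio with the background subtracted was 4.13, but the summed features stood at 51632 against 14898 CPM and those other than NTS1-2 at 20962 against 13169 CPM, so shared reads are argued against less there. Age and the level of Srp40 stay open, untested beyond these libraries, and more RNA from the ribosomal DNA spacer in old cells is a hypothesis, and handling in the ageing device and on magnets was not separated from age at 24 h or 48 h against 0 h.

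The iron regulon was higher in the MMP-low library. Its median log2 ratio was 1.769 among cells matched on total UMIs, which argues against the number of UMIs per cell as the whole cause. The median was 1.791 with the background subtracted, which argues against free RNA only as far as the barcodes taken as empty were empty. That was not tested in the high MMP library. Under TMM scaling the median was 1.404. That scaling moves all genes of a comparison by 1 constant, so this nearly repeats the 1.41 relative to all genes and is not separate evidence. The relative value itself argues against a shift common to all genes, as from abundant genes taking most of the counts. The mitochondrial state that the MMP ratio was sorted on stays open as a biological explanation, and was not tested beyond the single pair of libraries.

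The log2 ratios of the 2 sorts were negatively correlated across genes. Ribosomal protein, ribosome biogenesis and histone genes are argued against as the whole cause, since r was -0.370 without them. The listed stress, carbon source, hypoxia and iron genes did not carry it alone either, with r = -0.424 without them. Both removals took out only the listed genes, a small part of the 4794. They therefore cannot decide on wider programmes of growth, stress or carbon source. Among cells matched on total UMIs in both sorts r was 0.161. This met the outcome set beforehand for a difference in total UMIs per cell as the cause, so that explanation is not argued against. With every cell thinned to 1000 UMIs r was -0.284, against -0.412 over all cells. Thinning keeps the cells of unlike total in each tail, so it cannot decide on that explanation. Which cells are compared may matter, as matching leaves out cells of unlike total and thinning does not. Whether UMIs per cell reflect capture or the state of the cell was not tested, and a biological opposition of the sorted states stays open.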

How the results depend on the processing

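Chosen after seeing the data were the matching of cells on total UMIs, the split of cells into 3 equal groups by UMIs, the removal of ribosomal DNA features, the subtraction of each library's background, the minimum of 3 times the background mode, and correlations across genes under matching, thinning and equal weighting; the other settings were planned. No paired analysis was possible because each group holds 1 library, so no replicate could be left out. Of 7308 values of named genes under the alternatives, 4122 stayed inside their counting interval (21 with another sign) and 3184 moved out of it, 194 of these with another sign from ratios under 2-fold. Both values that turned from beyond 2-fold were of HO. Of 1448 list medians 1376 stayed within 1.5-fold and on their side, 38 moved and 34 turned. Counts of 2-fold genes stayed within 1.5 times in 131 of 180 cases, and numbers of clusters in 6 of 9. Correlations across genes stayed within 0.1 in 38 of 60 cases and those across cells in 42 of 51; in each set 7 turned from at least 0.1 in size and 1 more changed sign from a smaller value. Depth limits the MMP libraries most, with 8359838 and 4994385 UMIs in cells, and single values from few UMIs, such as DAN1 at 0 h (5 UMIs) and LSO1 in the high MMP library (8 UMIs). The daughter gene setting removed between 33.1% and 85.6% of cells, the most at 0 h. In the high MMP library 551 of 1107 cells passed 3 times the background mode. Scrublet called between 0 and 9 doublets per library, so that setting removes few cells.

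Values of results that moved or turned are given here, lists as median log2 ratios and genes at 2-fold as counts. The cause was not tested, except that a filter changes which genes enter each count and list, as does a scaling through the CPM minimum (in the MMP sort the zinc list had 7 measured members, and 6 under TMM). Time-course pairs share a library, and over all cells r was 0.342 for 24 h against 0 h with 48 h against 24 h (counting noise alone -0.526) and 0.595 for 48 h against 0 h with 48 h against 24 h (noise alone 0.561). The noise was not simulated under the alternatives, so no agreement is read from r of these pairs there. Under TMM scaling, 24 h against 0 h gave 131 genes lower and glycolysis -0.048. 48 h against 0 h gave 335 genes lower, glycolysis -0.18 and zinc 1.75. The Srp40 sort gave 49 genes higher and 45 lower. The MMP sort gave 589 genes higher, 412 lower and zinc -2.28. Under median-of-ratios scaling, 24 h against 0 h gave 94 genes lower and glycolysis -0.0018. For 48 h against 0 h it gave 317 genes lower, glycolysis -0.15 and zinc 1.77. For the Srp40 sort it gave 58 genes higher and 40 lower. For the MMP sort it gave 561 genes higher, 462 lower, heat shock -0.020 and zinc -2.33. With cells thinned to 1000 UMIs, 24 h against 0 h gave 748 genes higher, 149 lower, stress 4.33 and gluconeogenesis 3.50. Values for 48 h against 0 h were 236 genes lower. 48 h against 24 h gave 41 genes lower, stress -0.41, hypoxic -0.16 and silencing -0.16. Values for the Srp40 sort were 43 genes higher and amino acid -0.052. Values for the MMP sort were zinc -2.13 and M/G1 0.041. The value of r was -0.25 for 24 h against 0 h with 48 h against 24 h, 0.098 for 48 h against 0 h with 48 h against 24 h, -0.083 for 48 h against 0 h with the Srp40 sort, 0.280 for 48 h against 24 h with the Srp40 sort, -0.214 for 48 h against 24 h with the MMP sort and -0.284 for the Srp40 sort with the MMP sort. With every cell weighted alike, 24 h against 0 h gave 794 genes higher, 137 lower, stress 4.39 and gluconeogenesis 3.54. In the case of 48 h against 0 h it gave 231 genes lower. For 48 h against 24 h it gave 41 genes lower, stress -0.40 and hypoxic -0.19. In the Srp40 sort it gave RNA polymerase I -0.056. The value of r was -0.231 for 24 h against 0 h with 48 h against 24 h, 0.056 for 48 h against 0 h with 48 h against 24 h, -0.089 for 48 h against 0 h with the Srp40 sort, 0.351 for 48 h against 24 h with the Srp40 sort, 0.682 for 24 h against 0 h with the MMP sort and -0.258 for 48 h against 24 h with the MMP sort. Without cells holding 2 or more daughter gene UMIs, 24 h against 0 h gave 827 genes higher, 161 lower, heat shock 1.18, stress 4.95, gluconeogenesis 3.54, cell wall integrity 1.78, G1/S 0.42 and HO 2.54. 48 h against 0 h gave 227 genes lower, hypoxic 3.41, cell wall integrity 2.44, G1/S 0.57 and HO 3.25. Values for 48 h against 24 h were 54 genes lower, ribosomal protein 0.12, stress -0.59, hypoxic -0.56, alpha-specific 1.10 and silencing -0.071. The Srp40 sort gave 44 genes higher, 139 lower, RNA polymerase I -0.24 and hypoxic -1.41. In the MMP sort it gave M/G1 0.039. The rank correlation across cells was -0.030 at 24 h for the signatures.

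With no expression filter, 24 h against 0 h gave 623 genes higher, 41 lower and hypoxic 2.30. For 48 h against 0 h it gave 925 genes higher and hypoxic 2.45. In the case of 48 h against 24 h it gave 51 genes higher, 12 lower and RNA polymerase I 0.013. For the Srp40 sort it gave 43 genes higher. The MMP sort gave mitochondrially encoded -1.74. Under the filter of 500 UMIs and 100 CPM, 24 h against 0 h gave 203 genes higher, 17 lower and hexose transporter 2.72. Values for 48 h against 0 h were 293 genes higher, hexose transporter 2.65 and sulfur -0.30. 48 h against 24 h gave 1 gene lower, sulfur -0.14 and daughter cell 0.019. Values for the Srp40 sort were 12 genes higher, RNA polymerase I -0.25 and hypoxic -1.48. For the MMP sort it gave 606 genes higher and zinc -3.06. With a pseudocount of 10 CPM, 24 h against 0 h gave 17 genes lower, stress 2.96, hexose transporter 2.57 and hypoxic 2.99. In the case of 48 h against 0 h it gave 67 genes lower, stress 2.96, hexose transporter 2.11 and hypoxic 3.17. For 48 h against 24 h it gave 16 genes higher. In the Srp40 sort it gave 16 genes higher. Values for the MMP sort were gluconeogenesis 3.08. Taking barcodes of at least 1000 UMIs, the MMP sort gave mitochondrially encoded -2.0 and M/G1 0.042. With the cell threshold set from the top 3000 barcodes, 24 h against 0 h gave gluconeogenesis 0.98 and hexose transporter 2.73. 48 h against 0 h gave hexose transporter 2.59. Values for 48 h against 24 h were G2/M 0.0033. With all barcodes pooled, the Srp40 sort gave RNA polymerase I -0.010. The MMP sort gave 61 genes lower and M/G1 0.15. With an ambient share of 10% subtracted, the MMP sort gave zinc -1.96. Without the 5% of cells with the most UMIs, 48 h against 0 h gave 174 genes lower. At resolution 0.3, the cluster highest in hypoxic genes held 17.3% at 24 h and 18.7% at 48 h. At resolution 1.0, the clusters numbered 11 at 0 h, 13 at 24 h and 17 at 48 h. The cluster highest in hypoxic genes held 5.14% at 24 h and 5.91% at 48 h. Without scrublet doublets, the cluster highest in hypoxic genes held 11.4% at 24 h. Using Spearman's rho, the value was -0.056 for 48 h against 24 h with the Srp40 sort and 0.490 for 48 h against 24 h with the MMP sort. Over genes with 500 UMIs in every library, r was 0.491 for 48 h against 24 h with the MMP sort. For 25 genes per signature, rho across cells was 0.251 at 24 h for the signatures. For 100 genes per signature, rho across cells was -0.544 at 24 h for the signatures and -0.097 at 48 h for the signatures. Among cells matched on total UMIs, 24 h against 0 h gave hexose transporter 2.79. Values for 48 h against 0 h were hexose transporter 2.67. In the case of 48 h against 24 h it gave 13 genes higher, 8 lower, stress -0.28 and G2/M 0.079. For the Srp40 sort it gave 63 genes higher, 31 lower, RNA polymerase I -0.11 and ribosomal protein -0.072. The value of r was 0.049 for 24 h against 0 h with 48 h against 24 h, 0.313 for 48 h against 0 h with 48 h against 24 h, 0.143 for 24 h against 0 h with the Srp40 sort, 0.215 for 48 h against 0 h with the Srp40 sort, 0.255 for 48 h against 24 h with the Srp40 sort, 0.053 for 48 h against 24 h with the MMP sort and 0.161 for the Srp40 sort with the MMP sort. Without ribosomal DNA features, rho across cells was -0.033 at 24 h for the signatures. Among the 24 h cells with the fewest UMIs, rho across cells was -0.064 at 24 h for the signatures and -0.0041 at 24 h for the biogenesis and iron lists. Among those with intermediate UMIs, rho across cells was 0.042 at 24 h for the biogenesis and iron lists. Among those with the most UMIs, rho across cells was 0.035 at 24 h for the biogenesis and iron lists.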

Other observations

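All lists and genes in this part were picked for mention after their values were seen. Mitochondrially encoded genes, 8 in number, summed to 170.5 CPM at 0 h, 332 at 24 h and 560 at 48 h, to 355 and 331 in the high and low Srp40 tails and to 1299 and 212 in the high and low MMP tails. Capture of this RNA by the 3' kits was not tested, so these sums are not read as mitochondrial transcript levels. The 137 ribosomal protein genes summed to 375140 CPM at 0 h, 284020 at 24 h and 241110 at 48 h. Among cells thinned to 1000 UMIs the stress list was unevenly spread at 24 h, with a median of 10 UMIs and a 75th percentile of 56.8, against 12 and 34 at 48 h and 2 and 3 at 0 h. The median cell held 17 iron regulon UMIs in the low MMP tail and 3 in the high one. All 11 ribosomal DNA features took 5.16% of UMIs in the high Srp40 tail and 1.49% in the low one.

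HMRA1, annotated at a silent mating locus, stood at 368 CPM in the low and 189 CPM in the high MMP library, which carry the MATa allele of near-identical sequence, and at 1 UMI in the 48 h library and 0 in the other 4; the other silent locus genes had 0 UMIs in all 7 libraries, as did MATALPHA1, so these zeros do not show silence. At 48 h against 24 h further lists lay above their random lists, the silencing and ribosomal DNA maintenance genes (median log2 ratio 0.23), the unfolded protein response (0.20) and the alpha-specific genes (0.31). RNA polymerase I (-0.10), ergosterol (-0.10), G2/M (-0.11), phosphate (-0.13), daughter cell (-0.15) and biotin genes (-0.23) lay below. Under other settings RNA polymerase I turned to 0.013 (no expression filter), G2/M to 0.079 (matched cells) and 0.0033 (cell threshold from the top 3000 barcodes), and the daughter cell list to 0.019 (stricter filter). The silencing list turned to -0.16 in thinned cells and to -0.07 without cells holding daughter gene UMIs.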
